A study of Arabidopsis thaliana with 9 samples.

How the data were processed

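Gene expression was measured in inflorescence stems of Arabidopsis thaliana (ecotype Columbia-0) with an Affymetrix ATH1 array, on which each transcript is read by a set of short oligonucleotides, the probe set. Per the labels' protocols, plants were 1.5 months old and grown under 16 h of light and 8 h of darkness, stems were frozen and ground, and 1.5 µg of total RNA per sample was labelled with biotin. The 9 arrays fall into 3 groups of 3: an RNA interference line against HCT, the loss-of-function mutant ccr-1, and the wild type. Groups and replicate numbers were taken from the labels. The numbers run from 1 to 9 without repeats, so they pair no samples across groups. Nothing in the labels says that the 3 arrays of a group came from separate plants, so the p-values measure the spread between these arrays, which may be technical.

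RMA and MAS5 are named in the submitters' processing notes, and their versions and settings are not given in the sources used here. The values used are intensities deposited by the authors on a linear scale, 1 per probe set and array, with nearly equal quartiles on all arrays. RMA combines background correction, quantile normalization across arrays and a robust summary of the probes in a set, which compresses changes near the floor and makes the arrays' distributions alike, so changes in total RNA per cell cannot be seen. The median log2 intensity lay between 6.92 and 7.04 on the 9 arrays. A second table deposited by the authors holds 3785 of the probe sets with the same intensities (largest difference 0), a detection call per array (present, marginal or absent), the ratio of linear group means, p-values and a category for each comparison. The authors' ratio decides the category: the lowest ratio in the up category was 2.00 in each comparison. The authors' p-values named Pts are those of an equal-variance test on the linear intensities, since recomputed values differed by at most 2.14e-06 on the log10 scale. The test behind their other p-value column is not given in the sources used here. No p-value of that table was used below.

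The plan made before the data were examined took the deposited RMA values to be on a log2 scale. They are linear, so log2 was taken here before testing. The 64 control probe sets were left out, and 22746 were tested. The fit used limma 3.58.1 in R 4.3.3 with a mean per group over all 9 arrays (lmFit, contrasts.fit, eBayes), so that the 3 groups shared an estimate of the spread, with Benjamini-Hochberg adjustment over all probe sets. A probe set was called at an adjusted p under 0.05, and the number called with at least a 2-fold change is given as well. Changes are log2 differences between group means, ± the standard error of the fit, with n = 3 arrays per group. Adjusted p-values of genes are from this fit. The number of arrays limits the precision. The same code was tested on simulated data for the comparison of HCT-RNAi with wild type over 22746 probe sets, of which 50 were changed at each of 4 sizes: it called 10% of those changed by 0.25, 88% of those changed by 0.5 and 100% of those changed by 1 or 2 on the log2 scale, and 12 of its 161 calls were false. Only 200 probe sets were changed there, whereas 13783 were called in the data, and the Benjamini-Hochberg cutoff loosens as more probe sets change. These rates therefore do not describe the calls below. Of 31 simulated sets of 12 members, 5 were shifted by 0.5 in the same comparison. Camera recovered 5 of these 5, with 0 false calls among the unshifted sets. That simulation used all 22746 probe sets as background, so it does not describe the test within the authors' table reported below. It also drew each probe set independently, so it does not cover lists whose members are correlated.

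Probe sets were named from the platform annotation (1 gene for 13513 of them, several genes for 503, none listed for 8730) and, where that was silent, from the locus column of the authors' table, with symbols from a RefSeq gene table. Probe sets whose suffix marks transcripts shared by related genes (1061), and 31 others for which the sources differed, were left unnamed. This gave names to 14884 probe sets and 14754 genes, and left the others unnamed here. No coordinates are given, since no genome build is named.

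There were 31 gene lists with 492 entries, fixed before the data were examined. Of these entries, 279 had a name here and 246 of those lay in the authors' table, in which nearly every probe set with a 2-fold change in some comparison is listed. The named members are therefore enriched for changed genes. For this reason the gene set test, camera with a preset correlation of 0.01, compared each list's members in that table with the other probe sets of that table, where a list had at least 3 such members, and was adjusted by Benjamini-Hochberg over the lists tested. It asks whether members moved further up or down than other probe sets chosen by the authors on these arrays, so the counts of changed members are not independent evidence. That choice of background was made after the annotation was seen. Camera was repeated with an estimated correlation, with which 0 of 25 lists passed in each comparison (6, 8 and 4 had an unadjusted p under 0.05 for HCT-RNAi and ccr-1 against wild type and for ccr-1 against HCT-RNAi). Fry, a self-contained test of whether members move one way on balance, called 23, 24 and 23 lists.

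Genes named in the text were picked by a rule written before the data were examined. Per comparison they are the 8 largest rises and 8 largest falls among probe sets with 1 gene, a call and groups that do not overlap. To these come up to 4 called members, by size of change, of each list that passed camera or had at least 1 in 4 named members called. HCT, CCR1, PR1, PR2, PR5 and ADPG1 are always given, and fewer may be named from the end of each order. Members that moved against the majority of their list or did not pass, the photosynthesis, phloem and xylem members beyond this rule, and the genes of lists added later were chosen after their values were seen. A gene of a list is represented by its probe set with the highest mean. A gene called absent or marginal on all 3 arrays of a group has only a bound there: its change is given as at least N-fold, the brighter group's mean against, per array, the higher of the gene's own value and the lowest value called present on that array. Detection calls were used only where the authors' table lists the probe set.

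Chance overlap between the comparisons that share the wild-type arrays was simulated with 100 sets of unchanged groups. Alternatives covered filters on dim probe sets (mean log2 intensity of at least 5 or 6 in a group), repeated quantile normalization, median centring, fits of 6 arrays, an intensity trend with robust variances, array weights, 1 probe set per gene, a minimum change of 0.5 in the test, each array left out in turn, and 2 other gene set tests. A repeat with the other deposited table was not run, because its values are identical. Other backgrounds for camera and the 2-fold threshold as an alternative were added after seeing the data, as were lists of seed tissue, embryo, circadian clock and copper genes.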

Results

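The series compared stems with reduced activity of either of 2 lignin enzymes with wild-type stems. HCT (hydroxycinnamoyl-CoA:shikimate hydroxycinnamoyl transferase) acts in the middle of the monolignol pathway, and CCR1 (cinnamoyl-CoA reductase) catalyses the first step specific to lignin monomers. Stems of an HCT-RNAi line, of the ccr-1 mutant and of the wild type were each represented by 3 arrays. Replicate arrays of a group correlated at 0.997 to 0.999 over all probe sets, and arrays of different groups at 0.949 to 0.960. The median standard deviation between replicates was 0.07 in wild type, 0.07 in HCT-RNAi and 0.08 in ccr-1 on the log2 scale. The log2 signal from the 3' end of actin exceeded that from its 5' end by 4.36 ± 0.02 (SD, n = 3) in HCT-RNAi, 3.98 ± 0.06 in wild type and 3.86 ± 0.04 in ccr-1, and for GAPDH by 1.78 ± 0.12, 1.46 ± 0.06 and 1.61 ± 0.05. The first principal component carried 52.7% of the variance and the second 43.3%. Most genes of the lists below could be named only through the authors' table, which holds probe sets selected for change on these arrays, so the share of changed members is inflated and is not independent evidence of a list's direction.

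The targeted gene was lower in each line. HCT (AT5G48930) had a mean log2 intensity of 12.50 in wild type and 8.97 in HCT-RNAi, an 11.5-fold lower level (log2 change -3.53 ± 0.05, SE, n = 3 arrays per group; adjusted p = 1.33e-13). CCR1 (AT1G15950) fell in ccr-1 from 11.87 to 10.07 (-1.81 ± 0.06, adjusted p = 7.84e-11). Each enzyme's transcript was also lower in the other line, though by less: CCR1 fell by 0.76 in HCT-RNAi and HCT fell by 0.55 in ccr-1 on the log2 scale. In direct comparison, HCT was 2.98 ± 0.05 higher in ccr-1 than in HCT-RNAi on the log2 scale, and the CCR1 difference was -1.05 ± 0.06. Where the probe set lies relative to the ccr-1 lesion is not given in the sources used here. ADPG1 (AT3G57510), a polygalacturonase of abscission and dehiscence zones that cuts pectin, was called present on none of the 3 wild-type arrays and on all others. It was at least 35.1-fold higher in HCT-RNAi and at least 90.4-fold higher in ccr-1, and 1.37 ± 0.08 higher in ccr-1 than in HCT-RNAi on the log2 scale. On the same arrays floral organ markers rose by a median of 1.96 in HCT-RNAi and 3.18 in ccr-1. Seed storage markers rose by a median of 8.54 in ccr-1. Whether the ADPG1 signal came from the stem axis or from such organs was not tested.

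**Figure D1:**
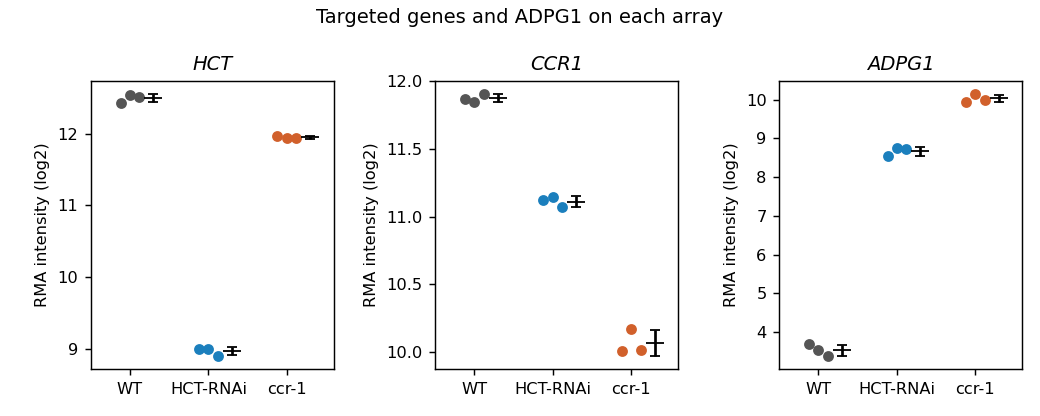
RMA intensity (log2) of HCT, CCR1 and ADPG1 on each of the 9 arrays, with a dot per array and a bar for the mean ± SD (n = 3) of each group. HCT is lowest in HCT-RNAi (mean 8.97), CCR1 is lowest in ccr-1 (mean 10.07), and ADPG1 is lowest in wild type (mean 3.53).

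The first comparison asked which transcripts differ in stems with reduced HCT. In HCT-RNAi stems, 8 of 9 genes of monolignol synthesis fell, the targeted HCT among them. Also lower were 16 of 16 genes of secondary wall cellulose and xylan and 14 of 16 secondary wall transcription factors. Of the genes of pattern and elicitor responses 12 of 14 fell, and of those of touch and wounding 8 of 9. Rises were found in 15 of 16 flavonoid and anthocyanin genes and in 9 of 9 floral organ markers. These lists passed camera, and none of them passed with an estimated correlation, where the adjusted p was 0.171 for monolignol, wall and touch genes, 0.148 for the transcription factors, 0.117 for pattern and flavonoid genes and 0.135 for floral markers. The largest rises were in GPT2 (AT1G61800), a plastid glucose-6-phosphate translocator, by 7.44 ± 0.09, and in CORI3 (AT4G23600), a coronatine- and jasmonate-induced gene, by 7.38 ± 0.10. DFR, ABCB16, AT1G80130 and AT5G52390 followed at 5.67, 5.60, 5.44 and 5.39, and the lipid transfer protein gene LTP2 rose by 5.10. The largest fall was in AT1G66240, annotated as ATX1, a relative of copper chaperones, which was at least 57.7-fold lower. AT3G15450 (-4.88 ± 0.12), BT5 (-4.82 ± 0.09) and the transcription factor gene RAV1 (at least 27.8-fold lower) came next, then BXL2 at -4.73 and DIN10, a gene induced in darkness, at -4.53.

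In all, 13783 of 22746 probe sets were called between HCT-RNAi and wild type, 7476 higher and 6307 lower. With at least a 2-fold change there were 1152 higher and 1317 lower. In the authors' deposited table, 1150 probe sets were in the up category and 1317 in the down category. The groups did not overlap for 66.6% of probe sets, where chance gives 10%. The balance of directions depends on scaling: 54.2% of calls were higher with the deposited values and 39.5% after median centring of each array. Evening genes of the circadian clock rose by a median of 1.22 in HCT-RNAi and the named morning gene fell by 1.76 on the log2 scale. A different hour of harvest may therefore bear on any change in this comparison.

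Among genes of monolignol synthesis, 8 of the 9 named members fell and CCR2 rose by 0.36 in HCT-RNAi (9 called when adjusted over the list alone; camera adjusted p = 0.0103, adjusted p = 0.171 with an estimated correlation). The count and the set test include HCT, the target of the RNAi, and were not repeated without it. After HCT itself the largest falls were in PAL4, a phenylalanine ammonia-lyase, by 2.27, in the cinnamyl alcohol dehydrogenase gene CAD4 by 1.72, and in CSE by 1.14 on the log2 scale. Of 11 named laccases and peroxidases 6 fell, led by PRX71 (-3.54 ± 0.07), PRX64 (-2.61 ± 0.07) and LAC10 (-2.60 ± 0.12). PRX52 and PRX25 rose by 1.89 and 1.13, and 3 did not pass; the list did not pass camera (adjusted p = 0.194). The phenylalanine supply genes ADT5, ADT4 and DHS3, the 3 named of 12 listed, fell by 1.36, 1.24 and 0.90 on the log2 scale. All 16 named genes of secondary wall cellulose and xylan fell by at least 2-fold, with a median of -1.33, 16 called when adjusted over the list alone (camera adjusted p = 0.000317, adjusted p = 0.171 with an estimated correlation). FLA12, a fasciclin-like arabinogalactan protein gene, fell by 3.16 on the log2 scale, the xylan glucuronosyltransferase gene GUX1 by 1.95, and CESA7, a cellulose synthase subunit of the secondary wall, by 1.83. Of 16 named secondary wall transcription factors 14 fell, while MYB4 and XND1, which have repressor functions, rose by 0.56 and 0.79 (16 called when adjusted over the list alone; camera adjusted p = 0.0086, adjusted p = 0.148 with an estimated correlation), with MYB20 at -2.10 ± 0.06, NST2 at -1.97 ± 0.06 and MYB61 at -1.93 ± 0.06. Primary wall genes followed: 13 of 15 fell and the expansins EXPA1 and EXPA4 rose by 0.90 and 0.41. The largest falls were in XTH4 and XTH24, xyloglucan endotransglucosylase genes, at -2.45 and -1.88 (15 called when adjusted over the list alone; camera adjusted p = 0.0109, adjusted p = 0.135 with an estimated correlation). Markers of xylem cell death moved with the wall genes: the nuclease RNS3 and the metacaspase MC9 fell by 1.48 and 1.43 on the log2 scale, the protease XCP1 was 2.14-fold lower, and BFN1 fell by 0.22. The 4 markers had a median of -1.26 (camera adjusted p = 0.114), and the floral organ markers of the same arrays one of 1.96.

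Flavonoid and anthocyanin genes moved the other way in HCT-RNAi, on arrays whose floral organ markers had a median of 1.96. Of 16 named members 15 rose, all of them at least 2-fold, and the other, UGT78D1, was at 0.15 without a call; the median of the tested members was 3.17 (15 called when adjusted over the list alone; camera adjusted p = 2.21e-05, adjusted p = 0.117 with an estimated correlation). DFR, the reductase that commits flavonoids to anthocyanins, rose by 5.67 ± 0.09, the MYB activator PAP1 by 5.03 ± 0.05, and TT19, a glutathione transferase needed for anthocyanin storage, by 4.80 ± 0.06. Conjugating enzymes of phenylpropanoids also included large rises, in UGT84A2 by 3.35 and in UGT72E1 by 2.70, with 6 of 9 members higher and 1 lower (camera adjusted p = 0.194). Detoxification genes rose, 6 of 7, led by CYP81D11 at 3.02 ± 0.06 and GSTU1, at least 7.58-fold higher (6 called when adjusted over the list alone; camera adjusted p = 0.0384, adjusted p = 0.171 with an estimated correlation). Of 14 genes of abscisic acid, drought and cold response 11 rose, and COR47, ERD10 and LTI30 fell by 1.77, 1.05 and 0.28 on the log2 scale (14 called when adjusted over the list alone; camera adjusted p = 0.0326, adjusted p = 0.209 with an estimated correlation). COR15A was 3.54 ± 0.06 higher, the phosphatase HAI2 3.15 ± 0.07 higher, and LEA4-5 2.70 ± 0.06 higher.

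The salicylic acid, pattern and touch lists were lower in HCT-RNAi, beside the rise of floral organ markers (median 1.96). PR1 and PR2, markers of salicylic acid responses, had changes of -0.07 ± 0.09 and -0.15 ± 0.10 that did not pass (adjusted p = 0.527 and 0.188), while PR5 fell by 1.81 ± 0.07. PR1 changed sign to 0.04 when wild-type replicate 7 was left out. Of 16 members of the salicylic acid list 11 fell, led by UGT76B1 (-1.88), WRKY54 (-1.82), PR5 and WRKY70 (-1.77). ICS1, the isochorismate synthase of salicylic acid synthesis, and SARD4 rose by 1.31 and 0.68, and 3 did not pass (14 called when adjusted over the list alone; camera adjusted p = 0.0176, adjusted p = 0.209 with an estimated correlation). In the pattern and elicitor list 12 of 14 fell and 2 did not pass (14 called when adjusted over the list alone; camera adjusted p = 0.00247, adjusted p = 0.117 with an estimated correlation). There the transcription factor genes WRKY40 and WRKY18 fell by 3.54 and 3.36, and FLS2, the flagellin receptor, by 3.19 on the log2 scale. Touch and wounding genes fell, 8 of 9, with the calmodulin-like TCH3 at -3.13 ± 0.05, TCH4 at -2.86 ± 0.06 and ZAT10 at -2.66 ± 0.07 (9 called when adjusted over the list alone; camera adjusted p = 0.0176, adjusted p = 0.171 with an estimated correlation). CBF3, a cold response regulator and the remaining member, rose by 2.56. Jasmonate genes split. Of 21 named members 16 fell and 4 rose (20 called when adjusted over the list alone), with a median of -1.58 and a mean of -0.72 over those tested (camera adjusted p = 0.0252, adjusted p = 0.171 with an estimated correlation). CORI3, the lipoxygenase gene LOX2 (4.65 ± 0.07) and the thionin gene THI2.1 (4.57 ± 0.08) rose, whereas JAZ7, a repressor gene induced by jasmonate, fell by 4.51 on the log2 scale. The direction of this list turned when only the members named by the platform annotation were tested against all probe sets (median 1.26, adjusted p = 0.291).

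Markers of organs other than the stem axis also differed in HCT-RNAi. All 9 named floral organ genes rose, with a median of 1.96 (9 called when adjusted over the list alone; camera adjusted p = 0.0086, adjusted p = 0.135 with an estimated correlation). SEP2 was 3.32 ± 0.11 higher, AP3 at least 5.04-fold and SEP3 2.30 ± 0.07 higher. The 7 seed storage genes stayed between -0.29 and 0.28, with a median of -0.10. Of 6 phloem markers 3 rose and 3 fell, and of 11 epidermis and cuticle markers 5 rose and 6 fell, from PDF1 at 3.05 ± 0.08 to MAH1 at -2.75 ± 0.05. The photosynthesis list had 5 named members of 24, of which RCA (-0.40) and SBPASE (-0.29) were lower and 3 did not pass.

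**Figure D2:**
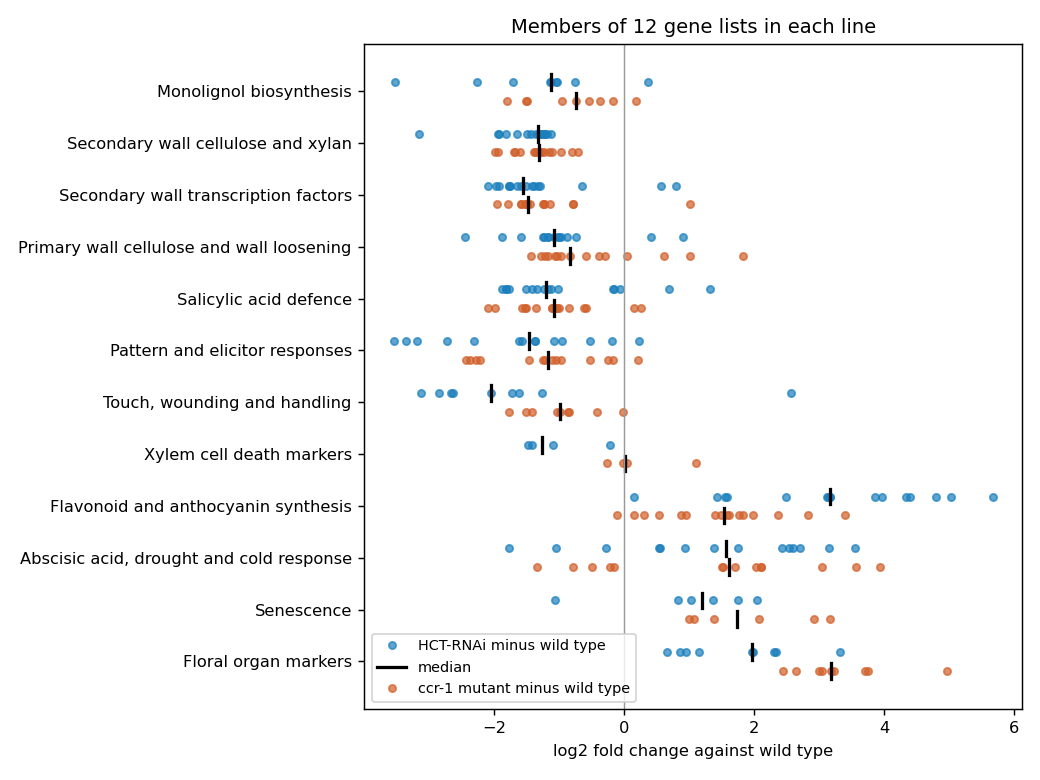
Log2 fold changes against wild type of the named members of 12 gene lists, with a dot per gene (blue HCT-RNAi, orange ccr-1) and a black bar at the median. Secondary wall genes lie near -1.3 in both lines (medians -1.33 and -1.32), whereas the xylem cell death markers lie at -1.26 in HCT-RNAi and at 0.01 in ccr-1.

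The second comparison asked the same of the ccr-1 mutant. In its stems 16 of 16 genes of secondary wall cellulose and xylan, 15 of 16 secondary wall transcription factors, 14 of 16 genes of salicylic acid defence and 12 of 14 of pattern responses fell. Of the flavonoid and anthocyanin genes 15 of 16 rose, and of the floral organ markers 9 of 9. These lists passed camera, and none passed with an estimated correlation, where the adjusted p was 0.127 for wall and salicylic acid genes, 0.0947 for flavonoid genes and 0.0752 for the others. All 3 ccr-1 arrays also held seed storage transcripts at high level, among them the 8 largest rises of the comparison. The 2S albumin genes SESA2 and SESA3 rose by 9.79 ± 0.07 and 9.48 ± 0.06, the 12S globulin genes CRA1 and CRU2 were at least 667-fold and 644-fold higher, SESA4 and SESA1 at least 566-fold and 373-fold, and CRU3 and the oleosin gene OLEO1 rose by 8.50 and 8.13. CRA1 had a mean log2 intensity of 13.43 in ccr-1 and 4.05 in wild type. The largest falls were in AT4G03156, at least 15.8-fold lower, in FAR6, an enzyme of fatty alcohol synthesis, at least 11.3-fold lower, and in XBAT34, RAV1 and BT5 by 3.23, 3.08 and 3.04 on the log2 scale.

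Between ccr-1 and wild type 12481 probe sets were called, 5625 higher and 6856 lower, and 1189 and 844 with at least a 2-fold change. In the authors' deposited table the up category held 1190 and the down category 844. The groups did not overlap for 59.3% of probe sets, against 10% by chance.

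All 16 named genes of secondary wall cellulose and xylan fell in ccr-1, 13 of them at least 2-fold, with a median of -1.32 (16 called when adjusted over the list alone; camera adjusted p = 9.36e-05, adjusted p = 0.127 with an estimated correlation). CESA7 fell by 1.99, GUX1 by 1.94, the chitinase-like gene CTL2 by 1.69 and CESA4 by 1.68 on the log2 scale. Transcription factors of the secondary wall fell in 15 of 16 cases, led by NST2 (-1.96 ± 0.06) and SND2 (-1.79 ± 0.06), NAC genes, and VND6 (-1.60 ± 0.13), a regulator of vessel formation (16 called when adjusted over the list alone; camera adjusted p = 0.000733, adjusted p = 0.0752 with an estimated correlation). XND1, a negative regulator of xylem formation, rose by 1.00. MYB4, which rose in HCT-RNAi, was among those that fell, and was 1.34 lower in ccr-1 than in HCT-RNAi on the log2 scale. Monolignol genes fell in 8 of 9 cases, with a median of -0.85 among those tested, and CCR2 rose by 0.17. CCR1 was followed by FAH1, ferulate 5-hydroxylase, at -1.52 ± 0.07 and CAD4 at -1.49 ± 0.07 (9 called when adjusted over the list alone; camera adjusted p = 0.0121, adjusted p = 0.17 with an estimated correlation). This count and this set test include CCR1, the gene mutated in ccr-1, and were not repeated without it. In the laccase and peroxidase list 8 of 11 fell, with LAC4 at -2.09 ± 0.06, and 3 rose, with PRX52 at 1.79 ± 0.08 and PRX25 at 1.63 ± 0.05 (camera adjusted p = 0.279). Xylem cell death markers did not move with these genes in ccr-1: XCP1 fell by 0.27, BFN1 rose by 1.11, and RNS3 and MC9 were at 0.04 and -0.01 without a call, for a median of 0.01. Floral organ markers had a median of 3.18 and seed storage markers of 8.54 on the same arrays.

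All 9 floral organ genes rose at least 2-fold in ccr-1, by a median of 3.18 (9 called when adjusted over the list alone; camera adjusted p = 0.00107, adjusted p = 0.0752 with an estimated correlation). SEP2 and SEP3 were 4.97 ± 0.11 and 3.76 ± 0.07 higher, AP3 at least 13.1-fold higher, and PI 3.22 ± 0.05 higher. The 7 seed storage genes rose by a median of 8.54 (7 called when adjusted over the list alone; camera adjusted p = 0.000733, adjusted p = 0.0752 with an estimated correlation). Pollen markers AGP11 and AGP6 rose by 1.93 and 1.78, and TUA1 fell by 0.25. Epidermis markers rose in 7 of 11 cases, with PDF1 at 3.41 ± 0.08, and MAH1 fell by 0.61 on the log2 scale (camera adjusted p = 0.15). Of the phloem markers SWEET11 rose by 1.32, SUS6 and SEOA were both 2.46-fold lower, and SEOR1 fell by 1.05 on the log2 scale. Senescence genes rose, 6 of 6, on these arrays that also held the floral and seed transcripts. SAG29 rose by 3.16 ± 0.07, the NAC regulator ORE1 by 2.93 ± 0.06 and SAG12 by 2.07 ± 0.09. All 6 were called when adjusted over the list alone (camera adjusted p = 0.0205, adjusted p = 0.17 with an estimated correlation). The rise was not limited to ccr-1. In HCT-RNAi 5 of the 6 rose, 4 of them at least 2-fold, with a median of 1.19 (camera adjusted p = 0.114). The other, SEN1, fell there by 1.06 on the log2 scale.

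Flavonoid and anthocyanin genes rose in 15 of 16 cases in ccr-1, 10 of them at least 2-fold, with a median of 1.57; the remaining gene, UGT78D1, was at -0.11 without a call (15 called when adjusted over the list alone; camera adjusted p = 0.00107, adjusted p = 0.0947 with an estimated correlation). DFR, PAP1 and TT19 led, at 3.40, 2.82 and 2.36. On the same arrays the floral organ markers had a median of 3.18 and the seed storage markers of 8.54. Genes of abscisic acid and drought response did not pass as a list (camera adjusted p = 0.0873), with 9 of 14 higher and 4 lower. HAI1 rose by 3.94 ± 0.06 and LEA4-5 by 3.57 ± 0.06.

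The salicylic acid, pattern and touch lists fell in ccr-1, beside the rise of floral organ markers (median 3.18) and seed storage markers (median 8.54). PR1 fell by 1.01 ± 0.09 on the log2 scale, PR2 fell by 1.03 ± 0.10 and PR5 fell by 1.99 ± 0.07. In the salicylic acid list 14 of 16 fell and SARD4 rose by 0.26, with WRKY54 at least 4.30-fold lower and the PR1 regulator NIMIN1 at -1.57 ± 0.10 (15 called when adjusted over the list alone; camera adjusted p = 0.00107, adjusted p = 0.127 with an estimated correlation). In the pattern and elicitor list 12 of 14 fell and 2 did not pass, led by WRKY53 (-2.43), FLS2 (-2.38) and WRKY40 (-2.29) (12 called when adjusted over the list alone; camera adjusted p = 0.00142, adjusted p = 0.0752 with an estimated correlation). Touch and wounding genes fell in 8 of 9 cases, TCH3 by 1.78, ZAT10 by 1.51 and SZF1 by 1.41 on the log2 scale, and CBF3 was at -0.02 without a call (8 called when adjusted over the list alone; camera adjusted p = 0.00867, adjusted p = 0.127 with an estimated correlation). Jasmonate genes had 15 lower and 4 higher of 21, with a median of -0.80 and a mean of 0.04 over those tested, and did not pass (camera adjusted p = 0.0565). THI2.1, CORI3 and LOX2 rose by 6.48, 5.45 and 4.00, and the methyltransferase gene JMT by 2.62.

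**Figure D3:**
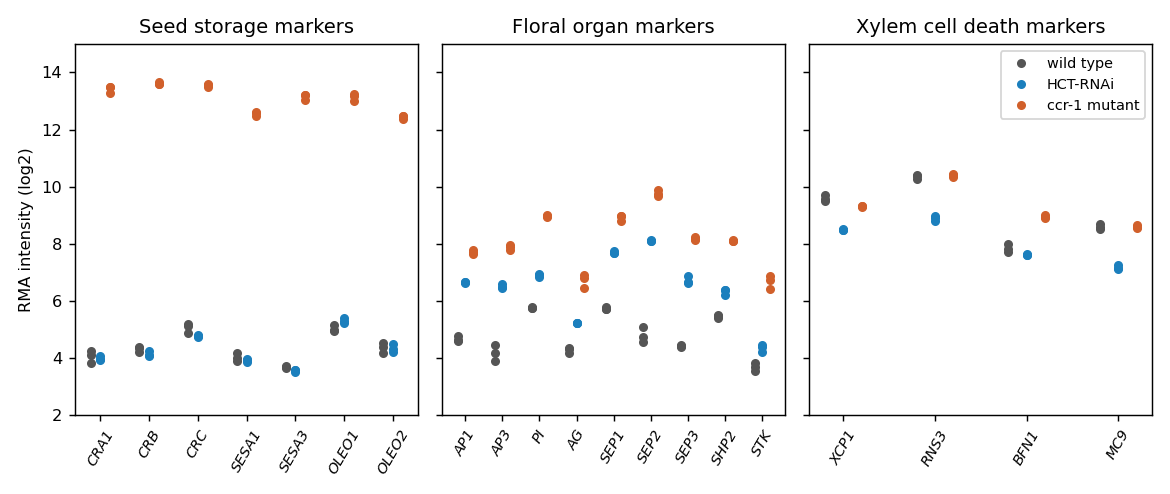
RMA intensity (log2) of seed storage, floral organ and xylem cell death markers, with a dot per array (grey wild type, blue HCT-RNAi, orange ccr-1; CRB and CRC are other names of CRU2 and CRU3). Seed storage genes are high on ccr-1 arrays only (CRA1 mean 13.43, against 4.05 in wild type), floral genes rise from wild type through HCT-RNAi to ccr-1, and RNS3, XCP1 and MC9 are lowest in HCT-RNAi.

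The lines were also compared directly. All 7 seed storage and all 9 floral organ genes were higher in ccr-1, and 14 of 16 flavonoid and anthocyanin genes were higher in HCT-RNAi. These lists passed camera but not with an estimated correlation (adjusted p = 0.0823 for seed storage, 0.181 for floral organs and 0.0823 for flavonoids). The secondary wall genes of cellulose and xylan had a median difference of 0.01. Above HCT-RNAi, ccr-1 had SESA2 and SESA3 by 9.82 ± 0.07 and 9.61 ± 0.06, and CRA1 by at least 704-fold. The largest falls from HCT-RNAi to ccr-1 were in GPT2 (-4.23 ± 0.09), the wall-modifying gene XTH31 (-3.92 ± 0.07), the anthocyanin activator PAP2 (-3.80 ± 0.10), the debranching enzyme gene ISA3 (-3.61 ± 0.07) and APL4 (-3.61 ± 0.08), a subunit of ADP-glucose pyrophosphorylase. In all 13406 probe sets were called, 5773 higher and 7633 lower in ccr-1, with 1091 and 676 at least 2-fold. The share of calls that were higher was 43.1%, and 53.8% after median centring. In the authors' deposited table the categories held 1092 and 675.

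Of 16 flavonoid and anthocyanin genes 14 were lower in ccr-1 than in HCT-RNAi and FLS1 was 0.35 higher, with UGT75C1 at -2.98 and 5MAT at -2.85 after PAP2 (15 called when adjusted over the list alone; camera adjusted p = 2.62e-05, adjusted p = 0.0823 with an estimated correlation). Among 16 secondary wall cellulose and xylan genes 7 were higher, CESA4 and GAUT12 were lower (-0.44 and -0.31) and 7 did not pass, with a median difference of 0.01 and an SD of 0.53 over the members; FLA12 had the largest difference, 1.82 ± 0.05 (camera adjusted p = 0.955). The xylem cell death markers were all higher in ccr-1, RNS3 by 1.51, MC9 by 1.41, BFN1 by 1.33 and XCP1 by 0.83 (camera adjusted p = 0.136). Pectin genes were higher in 9 of 10 cases, the xylosidase BXL1 by 3.05 and the galactosidase BGAL1 by 2.43. Of these, 9 were called when adjusted over the list alone (camera adjusted p = 0.0417, adjusted p = 0.283 with an estimated correlation). Against wild type 7 of the 10 fell and 2 rose in each line. The medians were -1.68 in HCT-RNAi and -0.74 in ccr-1 (camera adjusted p = 0.114 and 0.222). BXL1 and BGAL1 fell by 3.24 and 3.31 in HCT-RNAi on the log2 scale. Epidermis and cuticle genes were higher in 10 of 11 cases, led by the wax genes MAH1 at 2.13 ± 0.05 and CER4 at 1.84 ± 0.06 (10 called when adjusted over the list alone; camera adjusted p = 0.0417, adjusted p = 0.361 with an estimated correlation). On the same arrays the 9 floral organ genes were higher by a median of 1.49 (9 called when adjusted over the list alone; camera adjusted p = 0.0258, adjusted p = 0.181 with an estimated correlation), with the ovule gene STK at 2.34 ± 0.11, and the 7 seed storage genes by a median of 8.78 (7 called when adjusted over the list alone; camera adjusted p = 0.000983, adjusted p = 0.0823 with an estimated correlation). Salicylic acid genes split, 4 higher and 7 lower, with differences of -1.16 in ICS1, -0.94 in PR1 and -0.88 in PR2 (camera adjusted p = 0.514). Ethylene genes were higher in 7 of 7 cases, led by EBF2 at 1.77 ± 0.08 (camera adjusted p = 0.0714).

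Changes against wild type were compared between the lines. At the 2-fold threshold 542 probe sets were higher in both lines and 568 lower in both, where independent lists of the same sizes would share 60.2 and 48.9. Without that threshold 3605 were higher in both and 3881 lower in both, where independent lists would share 1849 and 1901. A further 1924 were called in opposite directions, 1286 of them higher in HCT-RNAi and lower in ccr-1. Across the 22746 probe sets, which are not independent replicates, the fold changes correlated at r = 0.57. In 100 simulated sets of groups without change that shared their wild-type arrays, the mean r was 0.50. With limma at most 0 probe sets were called in the same direction in both lines in those sets, and at most 326 had an unadjusted p under 0.05 in both, where the data had 8015. The covariance was 0.289, against 0.0034 in the simulation, a difference of 0.286. The 3 wild-type arrays could not be divided into separate controls of at least 2 arrays for each line, so a departure of the wild-type samples themselves, which the simulation does not cover, may be part of the overlap.

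**Figure D4:**
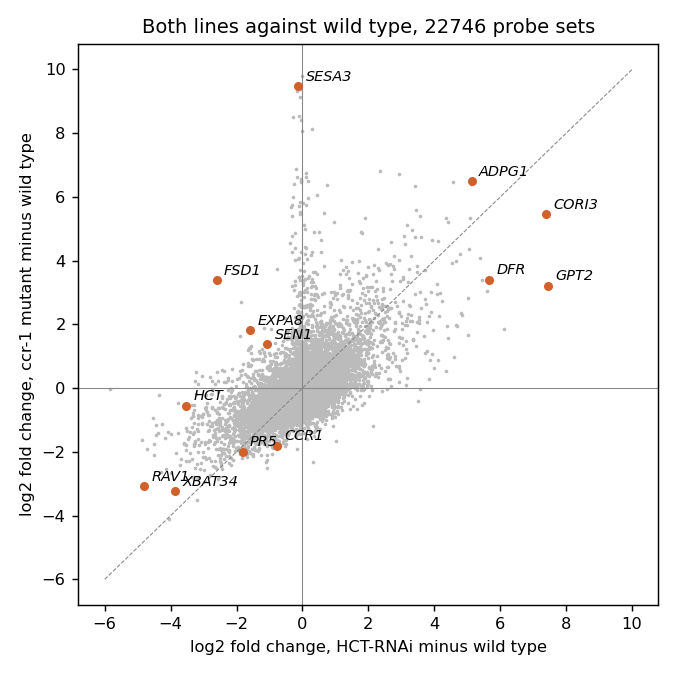
Log2 fold change against wild type of each of 22746 probe sets in HCT-RNAi (horizontal axis) and ccr-1 (vertical axis), with the dashed line marking equal change and named genes in orange. The changes correlate at r = 0.57, while seed storage genes such as SESA3 (9.48 in ccr-1) rise along the vertical axis.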

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

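The tests of the spike-in transcripts and of the signals from both transcript ends were chosen only after the values were seen. Groups of 3 arrays were not tested for single arrays that stand apart.

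In the lines 1924 probe sets were called in opposite directions against wild type. All of them also had a called difference between the lines, which opposite calls in the shared fit make certain, so this adds no support. Of the 1924, 20 changed at least 2-fold in each line. Of these 20, 18 fell in HCT-RNAi and rose in ccr-1. The others, AT4G16870 and AT4G34950, rose in HCT-RNAi (1.01 and 2.15) and fell in ccr-1 (-1.67 and -1.18). The naming rule also selects AT4G34950, while AT4G16870 is named here after its values were seen. In 2 of the 18 the gene belonged to a list fixed before the data were examined. EXPA8, an expansin gene, fell by 1.59 in HCT-RNAi and rose by 1.82 in ccr-1 on the log2 scale, a difference of 3.41 (adjusted p = 1.51e-12). SEN1, a gene of senescence and darkness, fell by 1.06 in HCT-RNAi and rose by 1.39 in ccr-1, a difference of 2.45 (adjusted p = 1.32e-09). Each of these genes had groups of 3 arrays that did not overlap.

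Control probe sets, left out of all tests, held a signal in ccr-1 as well. The 24 probe sets for the Bacillus transcripts dap, lys, phe and thr, which are added to RNA before labelling, were higher in ccr-1 than in wild type by a median of 0.81, with a range of 0.10 to 1.05, and in 21 of them every ccr-1 array lay above every other array. The median difference of HCT-RNAi from wild type was -0.01. The 3 probe sets of another Bacillus control, trp, lay between -0.07 and 0.03, but their intensities lay near the lowest signals called present on these arrays, where a change is hard to see. The 18 probe sets for hybridization controls, which are added after labelling, had medians of 0.11 in ccr-1 and -0.17 in HCT-RNAi. The probe set for 25S ribosomal RNA had an SD between arrays of 1.77 in ccr-1, 0.62 in wild type and 0.44 in HCT-RNAi.

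Signals from the 3' and 5' ends of control transcripts, whose difference grows as RNA is degraded or labelled less fully, differed between groups for some transcripts. For actin the difference was 4.36 ± 0.02 (SD, n = 3) in HCT-RNAi, 3.98 ± 0.06 in wild type and 3.86 ± 0.04 in ccr-1, and for GAPDH 1.78 ± 0.12, 1.46 ± 0.06 and 1.61 ± 0.05 on the log2 scale. In a second pair of actin probe sets it was 2.23 ± 0.11, 1.94 ± 0.06 and 2.04 ± 0.10. In these 3 pairs every HCT-RNAi array lay above every wild-type array, and every ccr-1 array lay below every wild-type array for actin in the first pair and above for GAPDH. In the second GAPDH pair (0.48, 0.41 and 0.36) and in both ubiquitin pairs the arrays of each line overlapped those of wild type.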

How the results depend on the processing

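The tests with other backgrounds for camera and the 2-fold threshold were chosen only after the results were seen. Over all alternatives, 165 of 191 counts and correlations stayed within 1.5 times the reported count or within the spread of the correlation (0.0087) and 26 moved. HCT in HCT-RNAi and CCR1 in ccr-1 kept direction and call in 36 of 36 cases. Of 6832 values of named genes 6723 kept direction and call, 107 lost the call, 1 gained it and 1 reversed: PR1 between HCT-RNAi and wild type was at 0.041 (adjusted p = 0.673) without wild type replicate 7, in a range of -0.14 to 0.041 over the arrays left out, and did not pass in any of them. In the order HCT-RNAi against wild type, ccr-1 against wild type and ccr-1 against HCT-RNAi, the numbers of called probe sets were 2469, 2033 and 1767 with at least a 2-fold change as well, 9024, 8263 and 8828 with 1 probe set per gene, where fewer features are tested, and 4364, 3560 and 3512 against a minimum log2 change of 0.5. Probe sets higher in both lines numbered 542 with the 2-fold threshold and 935 against the minimum change, and those lower in both 568 and 1086. The correlation of the fold changes was 0.58 with 1 probe set per gene. The gene lists that passed, 12, 10 and 5 as reported, numbered 0, 0 and 0 with an estimated correlation, 23, 24 and 23 with fry, 22, 18 and 16 for all named members against all probe sets, and 3, 3 and 2 for members named by the platform annotation alone, where fewer members are tested. Of 1017 list results 928 kept direction and call, 51 gained a call, 34 lost it and 4 reversed. The jasmonate list in ccr-1 turned from down to up with fry (adjusted p = 0.154), while its median stayed at -0.80 beside a mean of 0.04. With members named by the platform alone it reversed in ccr-1 (1.36, adjusted p = 0.172) and in HCT-RNAi (1.26, adjusted p = 0.291), and the laccase and peroxidase list reversed in HCT-RNAi (0.11, adjusted p = 0.535). The cause was not tested. Set tests were not rerun for 1 probe set per gene or the minimum change, and the alternative with the other deposited table was not run because its values are identical. Signal over background limits falls and rises from genes called absent, for which bounds are given.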

Other observations

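The tests on dilution by other organs and on time of day were chosen only after the results were seen, as were the lists of seed tissue, embryo, clock and copper genes.

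Among hormone and stress genes outside the groups above single genes were called, but no list tested against wild type in this paragraph passed camera. On the ccr-1 arrays the floral organ markers had a median of 3.18 and the seed storage markers of 8.54, and on the HCT-RNAi arrays the floral organ markers one of 1.96. Gibberellin genes rose in 7 of 8 cases in ccr-1, with GASA4 at 2.57 ± 0.05 and the synthesis gene GA20OX2 at least 4.47-fold higher, while GA2OX6, a catabolic gene, fell by 1.00 on the log2 scale (camera adjusted p = 0.0758). In HCT-RNAi 5 of the 8 rose and GA2OX6, GASA1 and GID1C fell by 2.11, 2.15 and 0.28 on the log2 scale (camera adjusted p = 0.414). Auxin-induced genes fell in 6 of 8 cases in HCT-RNAi, led by IAA19 (-2.15 ± 0.06), and in 5 of 8 in ccr-1, led by IAA29 (-1.69 ± 0.08), whereas GH3.6, which conjugates auxin, rose by 1.78 and 1.39 (camera adjusted p = 0.158 and 0.222). The chaperone gene HSP70 rose by 2.27 ± 0.06 in HCT-RNAi and by 1.32 ± 0.06 in ccr-1, in lists with 3 and 5 of 6 members higher and none lower (camera adjusted p = 0.121 and 0.106). Ethylene genes had 5 of 7 lower in HCT-RNAi, led by PR4 (-2.07 ± 0.07), whereas in ccr-1 4 of 7 fell and PR3, ACS2 (at least 2.73-fold higher) and EBF2 rose, PR3 by 1.91 ± 0.05 (camera adjusted p = 0.203 and 0.891). Genes of camalexin and indole glucosinolates split 3 to 3 in HCT-RNAi, where GSTU4 rose by 2.21 ± 0.08, and 4 of 6 fell in ccr-1 (camera adjusted p = 0.956 and 0.237). Of 4 aliphatic glucosinolate genes all rose in HCT-RNAi, led by MAM3 (3.24-fold), whereas in ccr-1 MAM3 rose by 2.28, MYB29 and BCAT4 fell by 0.60 and 0.14 on the log2 scale, and UGT74C1 did not pass. Of 18 cell cycle genes only AUR1 and AUR2 had a name here, and they rose by 0.21 and 0.75 in HCT-RNAi and by 0.19 and 0.44 in ccr-1. MOL1, the named cambium marker, rose by 0.67 in HCT-RNAi and was at 0.09 in ccr-1.

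Seed transcripts in ccr-1 reached beyond storage proteins. In a list of 17 embryo maturation genes, 16 had a name here and all 16 rose in ccr-1 by at least 1.22, with a median of 5.46, against 2 higher and 5 lower in HCT-RNAi, where the values lay between -0.35 and 0.35. The embryo regulators L1L (at least 3.53-fold), FUS3 (1.11), EEL (0.98) and BZIP53 (0.33) rose in ccr-1. Either seeds or siliques in the sampled material or an embryo programme in stem cells could give these values. Tissues around the embryo would come with seeds, and 2 of 6 named genes of seed coat and endosperm, TT10 (3.68) and MUCI10 (1.22), were called and at least 1 log2 unit higher, with SBT1.7 at 0.98. The list was chosen after the seed storage values were seen, and the rule was set before this count was made. By that rule 3 or more would have pointed to seeds and 1 or fewer to an embryo programme, so the count of 2 cannot tell them apart. Only 6 of the 19 listed genes had a name here, so a low count could have missed these tissues. Without the cut at 1 log2 unit, 5 of the 6 were called higher, 0 lower and 1 did not pass, with a median of 0.81. The rise of floral organ markers on these arrays (median 3.18) was not part of the rule.

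Secondary wall genes fell while transcripts of floral organs rose, and added RNA of other organs may dilute stem transcripts. Dilution as the whole cause would lower xylem cell death markers as much as wall genes. In ccr-1 the median of the 4 xylem markers (0.01) lay 1.33 above that of the 16 wall genes (-1.32, SD 0.37). The lowest marker was at -0.27. These values argue against dilution as the whole cause there only if the added organs do not express the markers, which was not tested. Senescence genes rose in 6 of 6 cases on the same arrays, with a median of 1.73. In HCT-RNAi the medians differed by 0.0693 (-1.26 against -1.33, SD 0.51), a value that dilution needs, though fewer wall-forming cells or lower expression in them would give it too. The 6 named phloem markers were not part of the test. They did not fall as a group in HCT-RNAi (median 0.23, 3 higher and 3 lower). In ccr-1 the phloem markers had a median of -0.56, with 2 higher, 3 lower and 1 that did not pass. All 3 falls were at least 2-fold, as dilution would give, while the rises go the other way. That median lies between those of the xylem markers (0.01) and the wall genes (-1.32), so it does not decide the question in ccr-1. An effect of reduced HCT or CCR1 on wall gene expression stays open and was not tested.

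Touch and wounding genes fell in both lines, and many of them vary over the day, so a different hour of harvest is a candidate explanation. In HCT-RNAi the 5 named evening genes of the circadian clock (GI, ELF4, PRR5, ELF3 and GRP7) rose by a median of 1.22 (0.94 to 1.27) and the named morning gene, RVE1, fell by 1.76 on the log2 scale, values that a later hour needs and that a shifted clock in the line itself would give too. In ccr-1 the evening median was 0.27 (-0.08 to 0.47) and RVE1 fell by 0.36, with 4 of the 6 genes called. Those values lie between the bounds set for the test, so a different hour and an effect of the mutation cannot be told apart in ccr-1. Hours of harvest are not given in the sources used here. A different hour would bear on every list of a comparison, not on touch genes alone, and the other lists were not tested for it.

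Among the 20 probe sets with opposite changes of at least 2-fold in each line, the iron superoxide dismutase gene FSD1 had the largest difference between the lines, 5.99 (-2.61 in HCT-RNAi and 3.39 in ccr-1). FSD1 rises when copper is scarce, so a copper status that differs between the lines may lie behind it. Copper protein genes would then move against FSD1. The 1 named gene of that kind, CCS, did so in both lines (0.20 in HCT-RNAi and -0.87 in ccr-1), so 1 of 1 fits and more than 1 would be needed to decide. Genes raised at low copper followed FSD1 in ccr-1 (COPT2 by 1.15 and YSL2 by 0.73 on the log2 scale, CCH by 2.47-fold). In HCT-RNAi COPT2 and YSL2 fell (-0.37 and -0.50) while CCH rose by 0.25, against FSD1. ATX1, the relative of copper chaperones with the largest fall in HCT-RNAi, was in neither copper list and was not part of this test.

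With 3 arrays against 3 there are 10 splits of the 6 arrays, too few for a share under 0.05. As many probe sets as in the real grouping were called by limma in 1 of 10 splits, the real grouping itself, in each comparison. For HCT-RNAi against wild type the real split called 13783 and the highest of the others 0, with 14561 and 259 at an unadjusted p under 0.05. For ccr-1 against wild type the numbers were 12481 and 0, with 13354 and 677 unadjusted, and for ccr-1 against HCT-RNAi 13406 and 0, with 14220 and 489 unadjusted. Each of the other splits mixes arrays of both groups, so the difference between the groups adds to the spread and lowers the calls. Their numbers are therefore no measure of what chance alone would call.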
